A study of Mus musculus with 141 samples.

How the data were processed

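Mouse glioma cells with the R132H mutation of IDH, cultured with AG-881 or DMSO, were sorted as live single cells into 96-well plates and profiled by joint single-cell reduced representation bisulfite sequencing and Smart-seq2, per the labels' protocols. DNA was cut with MspI, which enriches CpG-dense sequence, per the labels' protocols. The methylation table was used here, and the transcriptomes were not analysed here. Positions follow the mouse build mm10, per the submitters' processing notes. The aligner, the methylation caller and any read minimum are not given in the sources used here.

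The deposited table gives, for each cytosine position and cell, a methylated fraction that takes 3 different values, 0, 0.5 and 1, and is missing where the cell had no call. It holds 1416034 positions and 12325314 values for 141 cells, and 0.412% of the values are 0.5. The deposited fractions come without read counts, so the read depth behind a call is unknown and depth is given as the number of CpGs called. Column names gave the arm, the library pool and a barcode but not the well, so columns were assigned to arms and not to single wells. The number of columns per arm equalled the number of samples (67 and 74). All 141 columns differed in the set of CpGs they cover. Methylation at MspI fragments says little about CpG-poor sequence, and incomplete bisulfite conversion would raise every level.

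Positions on chromosomes 1 to 19 and X were used. Adjacent positions were taken as the 2 strands of 1 CpG and merged, which gave 1322177 CpGs, 89300 of them with both strands. Without a genome, adjacent cytosines of 2 neighbouring CpGs could not be told from such pairs. A CpG was called methylated in a cell above 50% and unmethylated below, and ties, 0.649% of calls, were left out. The level of a cell is the percentage of its calls that are methylated. Regions, gene ends and lists were compared at the 396065 CpGs called in at least 5 cells of each arm. Calls were pooled over cells, with Clopper-Pearson intervals per arm at the 95% level. Intervals of differences combine the intervals of both arms. They treat calls as independent and cover counting error only; calls of 1 cell in 1 window go together, so they are narrower than intervals over cells would be. Where 0 calls were methylated, the limit is 3 calls of the total.

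Cells are not replicates. The labels name 1 plate per arm and no separate cultures, so each arm was treated as 1 culture. No test was run, and SDs over cells are descriptions. The 4 pools of each arm served as technical batches. No pool holds cells of both arms, so pool and arm cannot be told apart within a pool. Comparisons of paired plate rows were replaced by comparisons between pools in order (1 with 5, 2 with 6, 3 with 7, 4 with 8), because wells could not be read from the columns.

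Gene positions came from the RefSeq table of GRCm38.p6, the same sequence as mm10, which gives both ends of a gene but no strand. Promoters, planned as 1 kb either side of a start, were therefore replaced by the CpG-denser end of each gene, the end with more CpG positions of the file within 1 kb. Genes with equal numbers at both ends were left out (5707 of 21631, of which 5376 had none). No genome was used, so CpG islands were replaced by the number of CpG positions of the file within 100 bp either side of a CpG. A gene end was measured with at least 50 calls and 10 cells per arm. Median depth was 206 calls with AG-881 and 187 with DMSO.

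Named gene ends had at least 200 calls and 20 cells per arm and the same sign in every comparison of paired pools with 20 or more calls in both. Pools were paired by order only, so which gene ends pass depends on that pairing. The 12 largest decreases and 12 largest increases among them were named, and in each list the measured members with the largest decrease and the largest increase. The thresholds and numbers in these rules, the 18 gene lists and most of the other settings tried were fixed before the data were examined. Gene ends and pools paired by order were not part of that plan and took the place of promoters and plate rows. The lists cover oligodendrocyte precursors, mature oligodendrocytes, astrocytes, neural progenitors, neurons, Notch, cell cycle, cell cycle inhibitors, microglia and immune cells, vascular cells and fibroblasts, imprinted genes, germline genes, Hox genes, developmental transcription factors, DNA methylation and IDH metabolism, antigen presentation, genes methylated in human IDH-mutant gliomas, and housekeeping genes. A list's median difference was placed among 10000 random lists of the same size matched on DMSO level and calls, as a description of these cells.

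For the level relative to other cells, each call of a cell at shared CpGs was set against the mean of both arms at that CpG, without the cell itself; this measure was chosen after seeing the data. Neighbouring CpGs and pairs of cells were compared with each cell thinned to 20000 CpGs. Alternatives changed the call rule, the cells, the CpGs, the weighting, the window and the pools. When alternatives left out cells or pools, the shared CpGs of regions, gene ends and lists were chosen again among the remaining cells. A minimum of 3 or 5 reads, summed reads or shares of reads could not be computed from fractions.

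The gene-end calculation was tested on simulated calls with the real coverage, in which 200 of 9033 gene ends differed between arms. Simulated differences averaging 14.6 and -14.1 points were recovered as 14.7 and -14.1 points, with the right sign at 197 gene ends. Intervals held the true difference at 97.1% of gene ends. Simulated calls were drawn independently of each other, so this does not show how well intervals cover in real cells, where calls go together. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.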

Results

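Single-cell reduced representation bisulfite sequencing was used to measure CpG methylation in mouse glioma cells that carry the R132H mutation of isocitrate dehydrogenase (IDH). The mutant enzyme makes 2-hydroxyglutarate, a metabolite that inhibits the TET enzymes, which remove DNA methylation. Cells had been cultured for more than 2 weeks with 1 µM AG-881 (vorasidenib, a brain-penetrant inhibitor of mutant IDH1 and IDH2) or with its vehicle DMSO, and live single cells were then sorted. The series asks whether such inhibitors drive lineage differentiation, and the question of this comparison is whether methylation differed between treated and vehicle cells. The data held 67 AG-881 cells and 74 DMSO cells, prepared as 4 library pools per arm (pools 1 to 4 for AG-881, pools 5 to 8 for DMSO). Each AG-881 cell had calls at a median of 89440 CpGs (range 23895 to 190259), and each DMSO cell at a median of 67749 CpGs (range 10438 to 165853). The labels name no separate cultures within an arm, so each arm counted as 1 sample: no difference below has a replicate check, and no p-value is given. Intervals are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only.

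Average CpG methylation per cell was slightly lower with AG-881 than with DMSO. The mean was 33.4% ± 3.61 (SD over 67 cells) with AG-881 and 34.3% ± 2.85 (SD over 74 cells) with DMSO, a difference of -0.905 percentage points that is within the spread of single cells in either arm. Library pools of one arm differed by more than the arms did. AG-881 pools 1, 2 and 4 averaged 31.2%, 31.6% and 33.1%, whereas AG-881 pool 3 averaged 36.8% and lay above every DMSO pool (33.1% to 35.4%). The difference between arms was -2.28 points without pool 3, -0.341 points without AG-881 pool 1, -0.258 points without AG-881 pool 2 and -0.443 points without DMSO pool 5, and its sign turned (0.121 points) when pools 1 and 5 were both left out. When each cell was instead set against the other cells at the same CpGs, which removes the effect of covering different regions, the AG-881 mean was -0.374 ± 1.26 points and the DMSO mean 0.319 ± 1.35 points (SD over cells), a difference of -0.693. On this scale AG-881 pools 1, 2 and 4 lay at -1.10, -0.457 and -0.515 points, and pool 3 at 0.357 points, inside the range of the DMSO pools (0.184 to 0.458). In all, 44 of the 67 AG-881 cells and 30 of the 74 DMSO cells lay below 0.

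**Figure D1:**
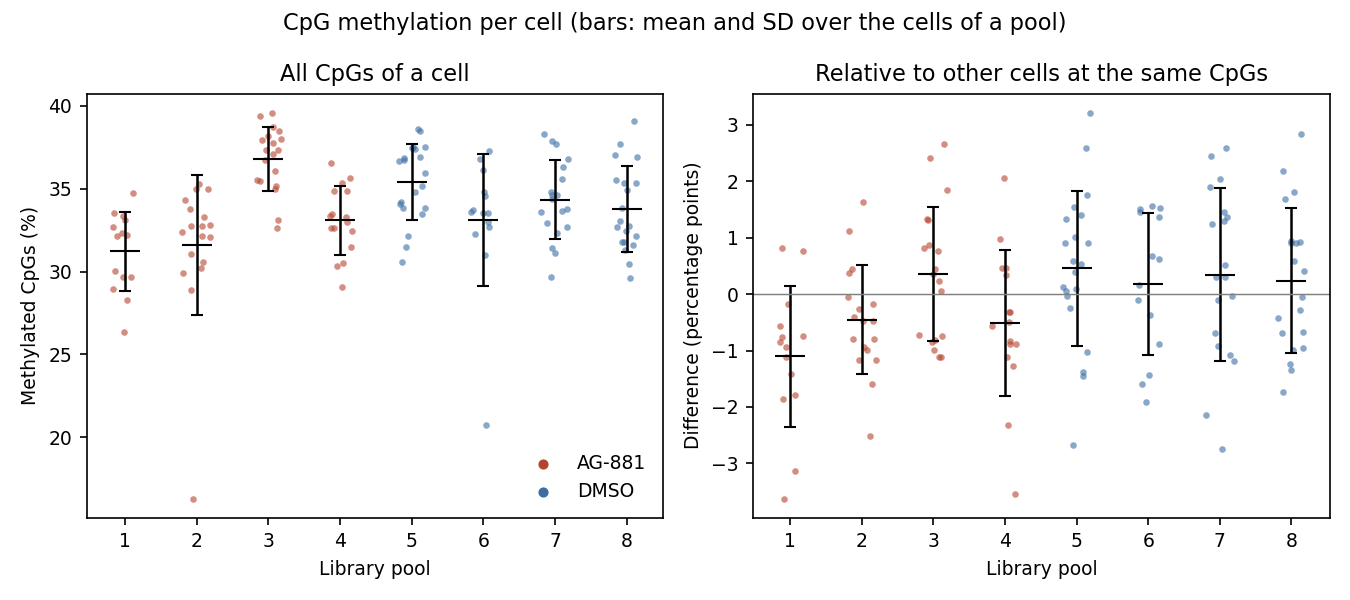
Methylation of each cell by library pool, in AG-881 (pools 1 to 4) and DMSO (pools 5 to 8) cells; points are cells and bars give the mean and SD over the cells of a pool. The left panel shows the percentage of a cell's CpG calls that were methylated, where AG-881 pool 3 averaged 36.8%, and the right panel the cell's level in percentage points relative to the other cells at the same CpGs, where pool 3 averaged 0.357.

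At the 396065 CpGs called in at least 5 cells of each arm, 25.4% of calls were methylated with AG-881 (interval 25.4 to 25.5, 3986573 calls) and 26.8% with DMSO (interval 26.7 to 26.8, 3655475 calls), a difference of -1.32 points. The difference was -0.821 points when every CpG had the same weight. Levels were lower with AG-881 in CpG-dense and CpG-poor sequence, but in CpG-poor sequence the difference came near 0 without any 1 of AG-881 pools 1, 2 and 4. Whenever a pool was left out here, the shared CpGs were chosen again, so the CpGs compared changed along with the pools. CpGs with 20 or more CpG positions within 100 bp, the sequence class closest to CpG islands, had 4.78% with AG-881 (interval 4.74 to 4.82) and 5.70% with DMSO (interval 5.65 to 5.75), which is 16.2% lower relative to DMSO. CpGs with 1 to 4 positions within 100 bp had 62% and 62.7%, which is 1.09% lower relative to DMSO. The difference was 0.155, -0.194 and -0.100 points without AG-881 pools 1, 2 and 4. AG-881 pool 4 had 62.1% in this class, near the level of its arm, so its level alone does not explain the value without it. Within 1 kb of an end of a protein-coding gene the levels were 6.78% and 7.59%, inside genes 40.5% and 42.2%, and outside genes 63.3% and 64.1%. Without AG-881 pool 1 the difference was -0.483 points inside genes and -0.0488 points outside genes. The level was lower with AG-881 on 19 of 19 autosomes, from -0.362 points on chromosome 12, where the interval (-0.768 to 0.0438 points) included 0, to -1.90 points on chromosome 4. Chromosome X had 50.4% with AG-881 and 49.9% with DMSO, and the interval of that difference (-0.0751 to 1.15 points) included 0. Pool 3 again differed from the rest of its arm: in the class with 20 or more CpG positions AG-881 pools 1, 2 and 4 had 4.10%, 4.66% and 4.48%, pool 3 had 5.99%, and the DMSO pools lay between 5.42% and 6.09%. Leaving out a single pool moved the difference at all shared CpGs to between -0.467 and -1.79 points, with the values nearest to 0 without AG-881 pools 4 (-0.467), 1 (-0.490) and 2 (-0.632).

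In percentage points, CpGs of intermediate methylation differed most. CpGs were sorted by their level in DMSO pools 5 and 6, and AG-881 was then compared with DMSO pools 7 and 8, so that chance in the sorting did not enter the comparison. CpGs sorted at 20 to 40% had 21.4% with AG-881 and 24% with DMSO, a difference of -2.63 points (interval -3.09 to -2.16). CpGs sorted at 40 to 60% had 43.3% and 45.9% (-2.66 points, interval -3.29 to -2.02), and those at 60 to 80% had 67.1% and 68.8% (-1.77 points). The classes at the extremes differed less in points: CpGs below 20% had 1.80% and 2.20% (-0.404 points), and those from 80% had 89.3% and 89.7% (-0.375 points). Relative to the DMSO level, however, the class below 20% was lowered most. In the class from 20 to 40%, pool 3 had 24.2%, above AG-881 pools 1, 2 and 4 (18.8%, 21.3% and 21%) and close to DMSO pools 7 and 8 (24.2% and 23.9%).

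**Figure D2:**
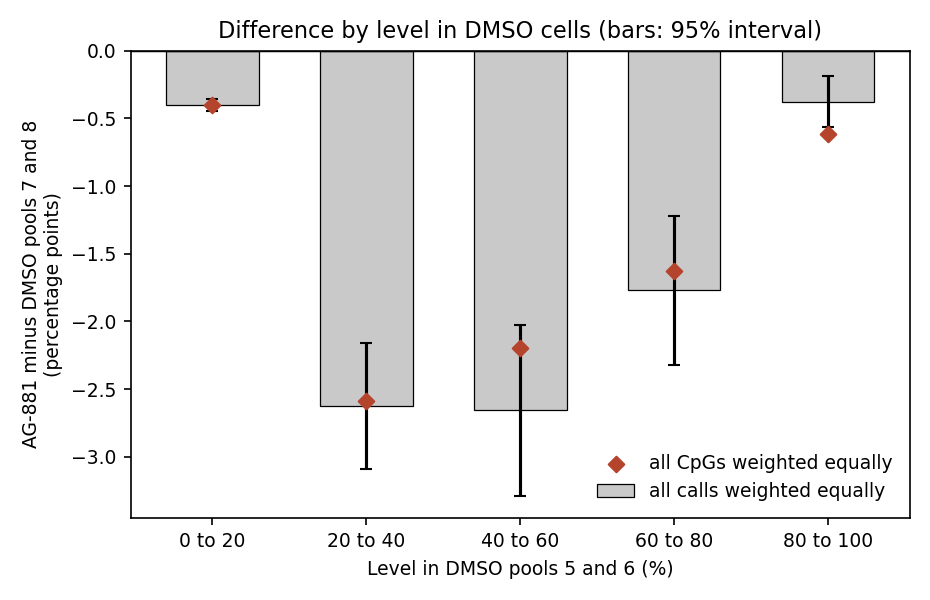
AG-881 minus DMSO pools 7 and 8, in percentage points, for CpGs sorted by their level in DMSO pools 5 and 6. Grey bars weight all calls equally and carry 95% intervals of counting error, and diamonds weight all CpGs equally; the bars reach -2.63 and -2.66 points for the classes from 20 to 60% and -0.404 and -0.375 points for the classes at the extremes.

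Methylation at single genes was read at the CpG-denser end of each gene, the end with more CpG positions of the file within 1 kb, which is often but not always the promoter end. Of 21631 protein-coding genes, 9033 had such an end with at least 50 calls and 10 cells per arm, and 6646 of these were below 5% in both arms. Gene ends with a mean level of 20 to 40% had a median difference of -4.55 points, and 73.4% of these 568 gene ends were lower with AG-881. Those of 40 to 60% had a median of -3.40 points. Percentiles between pools of one arm, which rest on fewer calls, were of similar size: the 1st and 99th percentiles were -15.7 and 9.59 points between arms, -16.5 and 10.7 points between AG-881 pools 1 and 2 and pools 3 and 4, and -13.1 and 15.8 points between DMSO pools 5 and 6 and pools 7 and 8.

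Among gene ends with at least 200 calls and 20 cells per arm and the same sign in every comparison of paired pools, the lowest relative to DMSO were led by Gjc1, Barhl2 and Rtn4rl1. The end of Gjc1, a gap junction connexin, at chromosome 11 from 102818686 to 102820686 (mm10), had 32.8% with AG-881 (interval 27.7 to 38.3, 320 calls) and 54.3% with DMSO (interval 47.7 to 60.9, 230 calls), but AG-881 pool 1 alone had 11.1% and the other AG-881 pools 37.5% to 43.4%. Barhl2, a homeobox transcription factor of the developing nervous system, on chromosome 5 from 106457166 to 106459166, had 18.7% (interval 15.1 to 22.7) and 35.5% (interval 30.8 to 40.4). Rtn4rl1, a Nogo receptor relative, on chromosome 11 from 75192993 to 75194993, had 31.8% and 48.1%. Rassf10 had 47.7% and 63.5%, Adcy3, an adenylate cyclase, 28.7% and 44.1%, and Adra2a, an adrenergic receptor, 33.5% and 47%. Prr5, which encodes a subunit of an mTOR complex, had 9.96% and 23.6%, and Rasgef1a, a Ras exchange factor, 18.5% and 31.9%. Papss2, which makes the sulfate donor of the cell, had 25.8% and 39.2%, Hsd11b2, a glucocorticoid-inactivating enzyme, 20% and 33%, and Fam89a 28.7% and 41%. AG-881 pool 4 alone had 5.56% at Hsd11b2 and the other AG-881 pools 17.6% to 37.3%. AG-881 pool 2 alone had 13.8% at Papss2 and the other AG-881 pools 28.1% to 33.3%. Sned1, an extracellular matrix gene on chromosome 1 from 93234796 to 93236796, had 2.80% (interval 1.13 to 5.68) and 14.1% (interval 10 to 18.9). Fam89a depended on the CpGs used: at CpGs called in at least 10 cells of each arm it had 48.4% with AG-881 and 41.2% with DMSO.

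The gene ends with the largest differences in the other direction reached lower sizes. Capn5, a calpain protease gene, on chromosome 7 from 98177946 to 98179946, had 27% with AG-881 (interval 21.9 to 32.6, 278 calls) and 10.8% with DMSO (interval 7.24 to 15.3, 250 calls), and every AG-881 pool (20% to 37.4%) lay above every DMSO pool (8.33% to 13.2%). Pdf, a mitochondrial peptide deformylase, had 23% and 10.4%, Fgd5, a Cdc42 exchange factor, 41.8% and 31.6%, and Vash2, a vasohibin, 21.1% and 13.2%. At Vash2, DMSO pool 8 (20.9%) lay above AG-881 pools 2 and 3 (20.4% and 17.6%), so its place among these genes depends on the pairing of pools. Gnai1, an inhibitory G protein subunit, had 8.47% and 1.51%, Tlnrd1, in a window shared with Mesd, 12.3% and 5.78%, and Slc35c1, the GDP-fucose transporter, 7.88% and 2.94%. Ccdc91 had 34% and 26.2%, Sympk, in a window shared with Foxa3, 6.58% and 2.80%, and the neural homeobox gene Cux2 9.84% and 7.01%, with intervals of the difference that included 0. Babam2 and Rbks share 1 window on chromosome 5 and had 4.38% and 0.847%, but 0% and 0.952% at CpGs called in at least 10 cells of each arm.

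**Figure D3:**
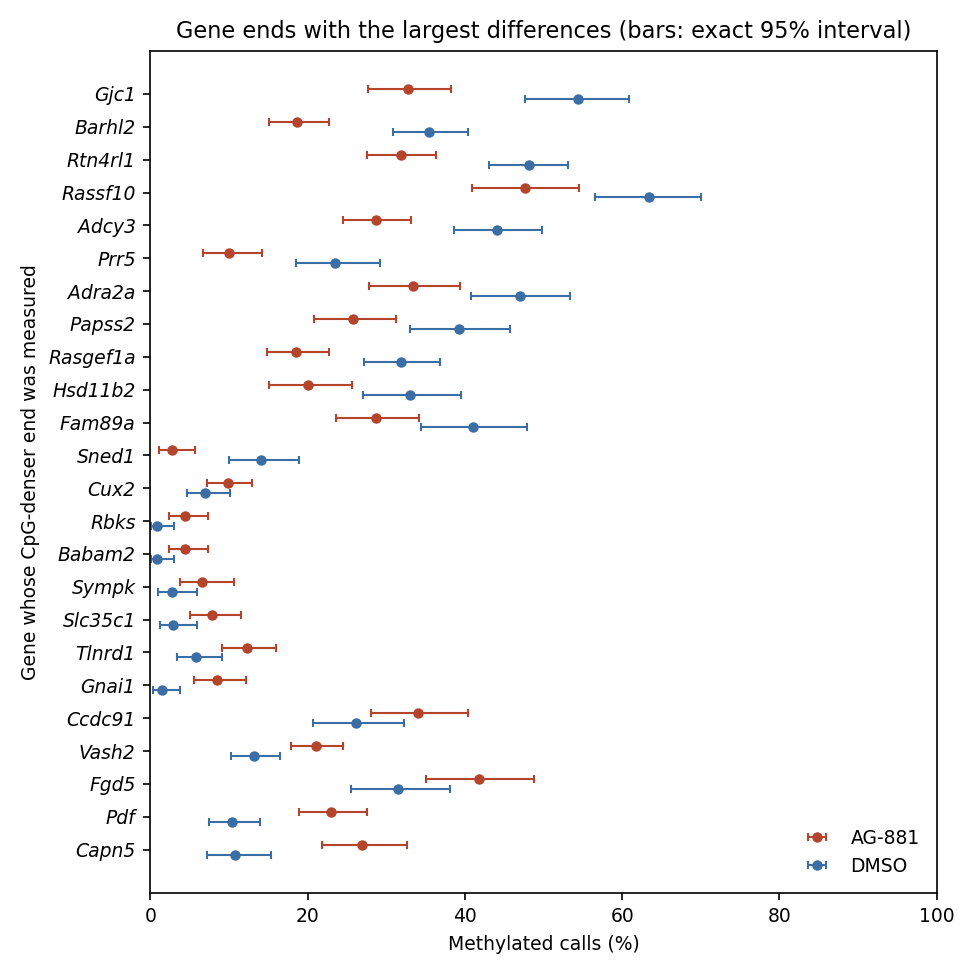
Percentage of methylated calls at the CpG-denser end of the 24 genes named by size, in AG-881 and DMSO cells; points are levels over all cells of an arm and bars exact 95% intervals of counting error. AG-881 lies lower at 12 genes, from Gjc1 (32.8% against 54.3%) to Sned1, and higher at 12 genes, led by Capn5 (27% against 10.8%).

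Glial lineage genes differed in both directions. Of 8 measured oligodendrocyte precursor genes, 4 were lower and 3 higher with AG-881, with a median difference of -0.236 points (percentile 68 among 10000 random lists of matched level and depth). The myelin regulator Sox10 had 42.7% with AG-881 (interval 32.7 to 53.2, 96 calls) and 57.8% with DMSO (interval 46.5 to 68.6, 83 calls), while Sox8 had 25.3% (interval 18.5 to 33.2) and 7.02% (interval 3.08 to 13.4). Of 6 mature oligodendrocyte genes, 3 were lower and 3 higher (median -0.588 points, percentile 77, and -3.48 points without pool 3). Among them were Ugt8a, which makes the myelin lipid galactosylceramide, at 45.2% and 61.8%, and the myelin enzyme Cnp at 24.8% and 17.1%, within counting error. At Ugt8a, AG-881 pool 1 had 30.9%, while pool 2, at 63.9%, lay inside the range of the DMSO pools (58.8% to 68.8%). Of 10 astrocyte genes, 7 were lower and 1 higher (median -0.873 points, percentile 13, and -0.260 points without pools 4 and 8). The glutamate transporter Slc1a2 had 3.87% with AG-881 (interval 2.27 to 6.13, 439 calls) and 14.9% with DMSO (interval 10.8 to 19.9, 255 calls), in every AG-881 pool (1.03% to 5.81%) below every DMSO pool (7.32% to 20.6%). The astrocyte connexin Gjb6 had 41.1% and 31.5% with overlapping intervals.

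Neural progenitor genes were mostly at low levels, while several neuron genes were more methylated. Of 15 progenitor genes, 7 were lower and 5 higher, with a median of 0 points (percentile 87.9). The homeobox gene Dlx2 had 17.9% with AG-881 (interval 14.8 to 21.3) and 28% with DMSO (interval 23.9 to 32.3). DMSO pool 8 alone had 14.0% at Dlx2, below every AG-881 pool (14.7% to 21.2%). Pax6, a regulator of radial glia, had 64% (interval 55.3 to 72) and 48.6% (interval 39 to 58.3). The Pax6 difference was 4.18 points without AG-881 pool 4, which alone had 80%, and within 500 bp of its end Pax6 had 30% and 34.4% instead. Of 8 neuron genes, 5 were lower and 2 higher (median -3.22 points, percentile 18.9, but 0.800 points without pools 1 and 5 and -1.39 points without pool 3); the glutamate receptor gene Grin1, in a window shared with Lrrc26, had 18% and 23.9% within counting error. The tubulin gene Tubb3, in a window shared with Mc1r, had 6.67% and 2.22%, but 2.58% and 2.42% without pool 3. Of 21 Notch pathway genes, 10 were lower and 8 higher (median 0 points, percentile 91). The ligand Jag2 had 26.7% and 41.4%, with overlapping intervals from 60 and 58 calls, and the Notch target Hey2 23.3% (interval 15.1 to 33.4) and 8.14% (interval 3.34 to 16.1). The other members at least 10 points higher, named after their values were seen, were the ligand Jag1 (21.3% and 9.15%) and the Notch target Hes1 (22.2% and 8.03%). Without pool 3 the AG-881 levels were 17.2% at Jag1, 17.5% at Hes1 and 22.9% at Hey2.

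Developmental transcription factors, whose CpG-rich genes are frequent sites of methylation in tumours, were mostly lower with AG-881, as were gene ends of intermediate level. Of 42 measured members, 29 were lower and 12 higher; 10 were lower by at least 10 points and 1 was higher by as much. Their median difference was -1.61 points (percentile 91.5), nearer to 0 than the -3.06 points typical of matched random lists. Their mean was -4.37 points (percentile 33). The median ranged from -4.25 points without pools 2 and 6 to -0.510 points without pools 4 and 8. The eye and pituitary regulator Six6 had 25.4% with AG-881 (interval 15 to 38.4, 59 calls) and 73.9% with DMSO (interval 61.9 to 83.7, 69 calls). AG-881 pool 1 had no calls at Six6, and only 1 pair of pools had 20 or more calls in both. AG-881 pools 2 and 4 had 24% and 12.5%, while pool 3, at 60%, lay inside the range of the DMSO pools (50% to 82.1%). The neural crest gene Foxd3 had 76% and 62.7% with overlapping intervals. Hox genes went both ways: of 20 measured members, 8 were lower and 10 higher, with a median of 0.482 points (percentile 99.1). That median was -1.38 points at CpGs called in at least 2 cells of each arm, -0.864 points with at least 10 cells and -1.86 points without pools 3 and 7, so its sign is open. Hoxa4 had 25.4% with AG-881 (interval 20.8 to 30.4) and 38.7% with DMSO (interval 33.1 to 44.5), and the window shared by Hoxa5 and Hoxa6 had 88.4% (interval 82.7 to 92.8) and 72.7% (interval 65.4 to 79.2), which counts for both genes. Of 10 imprinted genes, 5 were lower and 5 higher, with Peg10 and Sgce read from the same calls. The median of the list, 2.05 points (percentile 97.8), ranged from -12.6 points without AG-881 pool 2 to 9.31 points without pools 1 and 5. Igf2r, the insulin-like growth factor receptor gene, had 36% (interval 28 to 44.7) and 60.6% (interval 50.5 to 70), and Plagl1 28.3% and 22% within counting error. Of 5 genes methylated in human IDH-mutant gliomas, 4 were lower and 1 higher (median -4.51 points, percentile 26.3, but 0.855 points at CpGs called in at least 10 cells of each arm, -1.50 points without pool 3 and -0.379 points without pools 3 and 7), with the Wnt antagonist Sfrp1 at 49.4% and 57.6%, within counting error, and Rhof, in a window shared with Setd1b, at 0.578% and 0%, where 0 of 420 calls allows a level of up to 0.714%.

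Genes of DNA methylation and IDH metabolism had low levels in both arms, with list medians of 0.508% and 0.425%, and Tet1 had 9.01% and 11.1%. Of 19 measured members, 10 were lower and 5 higher (median -0.173 points, percentile 24.8), and the DNA repair dioxygenase Alkbh3 had 1.04% with AG-881 (interval 0.0264 to 5.67) and 10.3% with DMSO (interval 5.06 to 18.1), while the demethylase gene Kdm4b had 1.15% and 0%, where 0 of 337 calls allows up to 0.890%. Of 11 antigen presentation and interferon genes, 9 were lower and 2 higher (median -1.84 points, percentile 34.5, and -0.303 points without pools 1 and 5); the immunoproteasome gene Psmb9 had 25.5% and 35.6% and the peptide transporter gene Tap2 6.67% and 4.49%, both with overlapping intervals. Cell cycle genes (16 measured, median 0 points, percentile 51.3), cell cycle inhibitors (8 measured, median 0 points, percentile 62.2) and housekeeping genes (20 measured, median 0 points, percentile 57.4) had medians at or near 0% in both arms. In these lists the differences at Top2a (0% and 1.28%), Mcm3 (0.730% and 0%), Rbl1 (0% and 0.346%), Tbp (0% and 1.60%) and Rpl4 (1.32% and 0%, in a window shared with Zwilch) were within counting error, as was that at the imprinted inhibitor Cdkn1c (59.3% and 55.9%). Pooled over the housekeeping list, 0.208% of calls were methylated with AG-881 and 0.298% with DMSO. Only 3 germline genes were measured (median 0.652 points, percentile 70.1), with Hormad1 at 87.3% and 93.3% and Dazl at 87.7% and 84.2%, both within counting error. For cells of other types, no gene of the microglia and immune list was measured, and only Kdr (11.1% and 26.7%) and Flt1 (60.1% and 54.1%, within counting error) of the vascular and fibroblast list. At Kdr, AG-881 pool 3 had 36.4%, above every DMSO pool (20% to 35.3%), and the other AG-881 pools 0% to 9.68%.

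Chromosome coverage was alike in both arms on average. The median share of a cell's CpGs on a chromosome differed most on chromosome 5, with 7.56% in AG-881 cells and 6.81% in DMSO cells, and on chromosome 7, with 5.51% and 5.93%. An autosome was nearly missing, at no more than 0.25 of the median share of the arm, in 3 of 67 AG-881 cells (4.48%, interval 0.933 to 12.5) and in 2 of 74 DMSO cells (2.70%, interval 0.329 to 9.42), so a difference between arms was not detectable with these cell numbers.

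Methylation calls disagreed less often in AG-881 cells, within and between cells, but disagreement depends on the level, which was lower with AG-881 and was not adjusted for. With each cell thinned to 20000 CpGs, which left out 2 DMSO cells, neighbouring CpGs under 50 bp apart disagreed in 9.53% of pairs with AG-881 and 10.2% with DMSO (means over cells 9.63% ± 0.951 and 10.3% ± 0.908, SD over cells). AG-881 pools 1, 2, 3 and 4 had 9.47%, 9.18%, 9.89% and 9.56%, each below the lowest DMSO pool (9.98%). Without thinning that order did not hold for pool 3, which had 10.046% against 10.016% in DMSO pool 6. At CpGs called in both cells of a pair, 11.5% of calls disagreed between AG-881 cells, 12.5% between DMSO cells and 12.1% between cells of different arms.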

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

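Values are AG-881 minus DMSO in percentage points. Leaving out single pools, keeping strands apart, both gene ends, the level relative to other cells, unthinned cells, a limit of 0.5 and leaving out cells with a missing autosome were chosen after seeing the data. The global difference of -0.905 was -1.02 with calls pooled over cells, -1.22 at shared CpGs, -0.693 relative to other cells at the same CpGs and -0.793 in cells with at least 50000 CpGs (58 and 55 cells). Without single pools or pairs of pools it ranged from -2.28 to 0.121; the highest value, without pools 1 and 5, is the one with a reversed sign. The difference of -1.32 at shared CpGs was -0.896 with at least 10 cells per arm and -0.821 with equal weight per CpG, and ranged from -1.96 to -0.467 without pools. In the class with 20 or more CpG positions (-0.922) it was -0.847 with at least 10 cells, -1.09 with at least 2 and -0.753 with equal weight, and ranged from -1.15 to -0.640 without pools. Near gene ends (-0.808) it was -0.607 with at least 10 cells, -0.895 with at least 2 and -0.673 within 500 bp, and ranged from -1.07 to -0.408 without pools. CpGs with 1 to 4 positions within 100 bp (-0.684) ranged from -1.34 to 0.155 without pools, with the reversed sign without AG-881 pool 1. Neighbouring CpGs that disagree (-0.649) ranged from -0.808 to -0.495 without pools and were -0.685 under 150 bp. Cells with a nearly missing autosome numbered 2 with AG-881 and 0 with DMSO among cells with at least 50000 CpGs, and 6 and 5 at a limit of 0.5 of the median share. The causes of these shifts were not tested. For regions, gene ends and lists, leaving out a pool also changed the shared CpGs, so those values do not show the effect of the pool alone. The 58 named gene ends gave 1002 values under other settings, and 937 had the sign of the value in the text. Fam89a had 7.21, and Babam2 and Rbks -0.952, with at least 10 cells per arm, and the list of genes methylated in human gliomas 0.855. Pax6 had -4.43 within 500 bp. Without single pools or pairs, Babam2 and Rbks ranged from -1.49 to 6.85 and Tubb3 from -0.147 to 7.30. Minimums of 3 and 5 reads, summed reads, shares of reads and a window of 2 kb upstream to 500 bp downstream were not run, since the table gives neither reads nor strand. Keeping only calls of 0 or 1 on all strands gave -0.904 for the global level and -1.32 at shared CpGs. No paired analysis was possible because the labels name no separate cultures within an arm and the columns carry no replicate number.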

Other observations

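The tests on pool 3 other than that on conversion, and those on missing autosomes and copy number, were chosen after the result was seen; the wrong-label test was planned with fewer splits of the DMSO pools and widened to all splits after its first result. Calls on the strands of 1 CpG were also compared. Adjacent cytosines of neighbouring CpGs could not be told from such strand pairs. Whether differing strands reflect methylation upkeep was not tested. Where both strands of a CpG were called in a cell, they differed at 4.43% of CpGs with AG-881 (interval 4.36 to 4.50) and 4.89% with DMSO (interval 4.81 to 4.96). As a share of CpGs with methylation on at least 1 strand the values were 26.3% (interval 26 to 26.6) and 26.4% (interval 26 to 26.7), a difference within counting error. Chromosome Y calls were methylated at 70.1% with AG-881 and 71.1% with DMSO. Mitochondrial calls were methylated at 0 of 604 with AG-881 and 0 of 607 with DMSO, which allows up to 0.497% and 0.494%.

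Members of the Notch list at least 10 points higher with AG-881 were the ligand Jag1 and the Notch targets Hes1 and Hey2, and the members Notch3 (15.8% and 22.7%), Lfng (33.6% and 40.2%), Dtx1 (28.6% and 37.3%) and Heyl (37.1% and 43.1%) lay lower by less than 10 points, all within counting error. Among developmental transcription factors, the neural genes Gsx2 (32.9% with AG-881, 50.6% with DMSO) and Lhx5 (30.8% and 43.9%) and the kidney gene Six2 (44% and 56.1%) were among the 10 lower by at least 10 points. The imprinted gene Mcts2 had 25.7% and 40.5%. Within the gene list of DNA methylation, Dnmt3b, a methyltransferase, had 0.905% and 4.30%, and the oxygen sensor Egln3 1.23% and 8.64%, where the difference at Egln3 was within counting error. These genes were chosen after their values were seen.

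AG-881 pool 3 lay above the other AG-881 pools by 4.83 points in mean cell level. Of a gap of 3.95 points at shared CpGs, 2.93 points followed from the CpGs its cells covered. The remaining 1.02 points (counting interval 0.962 to 1.08) lay beside a range of 0.641 points among pools 1, 2 and 4. Covered regions thus gave most of the gap, and the rest exceeded counting error. Whether they are the whole cause stays open, as the rest was not above the bound of 2 times that range. Incomplete conversion is argued against by the lowest level class, where pool 3 exceeded the other AG-881 pools by 0.132 of its excess over all classes (0.386 with equal weight per CpG). Across 6277 gene ends, the covariance of a pool's difference from DMSO with that of other AG-881 pools, taken against separate DMSO pools, was 3.25, 2.05 and 3.06 squared points for pools 1, 2 and 4 but 0.264 for pool 3, a ratio of 0.0948 (0.0103 to 0.166 when any 1 chromosome was left out), and an exchange with a DMSO pool is argued against, since the highest DMSO pool had 1.12. Other values go with the label. With thinned cells, neighbouring CpGs disagreed less in pool 3 (9.89%) than in any DMSO pool, but this order did not hold without thinning. Pool 3 lay with AG-881 at Capn5 (20%) and Slc1a2 (4.40%). Both genes were named from values that include pool 3, so they cannot decide its label. Named gene ends also went the other way: at Igf2r pool 3 (51.2%) lay inside the range of the DMSO pools. Cell numbers go with the label too. Those of the pools equal, in order, those of the labelled plate-row pairs, and the DMSO pools hold all 74 labelled DMSO cells. DMSO pool 7 held 19 cells, as pool 3 did, so cell numbers alone do not exclude an exchange of these pools. As a hypothesis, pool 3 may hold cells of the DMSO arm under a wrong label, or treated cells with a weaker response. The matched transcriptomes would have to decide between these.

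A lower level in AG-881 at shared CpGs would also follow from better bisulfite conversion, but conversion moves unmethylated CpGs most. The difference in the lowest level class was 0.413 of that over all classes (0.580 with equal weight per CpG, above the bound of 0.5 set in advance, so a part from conversion is not excluded), and the difference at CpGs of 20 to 40% was 6.49 times that in the lowest class. Housekeeping gene ends differed by -0.0900 points (interval -0.293 to 0.102), less than the -0.404 points of the lowest class. Copy number of a few chromosomes is argued against by the lower level on 19 of 19 autosomes, of which chromosome 12 was within counting error. These levels were not adjusted for the CpGs each arm covered. Covered CpGs alone gave -0.523 points as a mean over cells at shared CpGs, so this argument is weak. Culture, plate and library preparation differed between arms in every cell, with 0 pools or plates holding cells of both arms, so these and an effect of the inhibitor cannot be told apart, and the latter is a candidate explanation only.

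An autosome was nearly missing in 5 cells, with 13 events. In AG-881 these were chromosomes 12 and 16 in a cell of pool 1, 6 and 15 in a cell of pool 2, and 2 and 14 in a cell of pool 3. In DMSO they were 6 autosomes in 1 cell of pool 5 and chromosome 16 in a cell of pool 7. Thinning deeper cells to the depth of each cell in blocks of neighbouring CpGs gave 0 such cells, but the thinned cells had been chosen for having no missing autosome, so low depth stays open. All 5 cells had fewer CpGs than the median of their arm, and the cell with 6 events had the fewest of all 141 cells (10438), so loss of template in cells with low recovery may account for them; loss of the chromosome in the cell was not tested.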
